A study of Homo sapiens with 4 samples.

How the data were processed

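RNA was measured in 4 libraries from U2OS cells, an established human osteosarcoma line, by native nuclear RNA immunoprecipitation and sequencing (nRIP-seq). In this assay a nuclear lysate is incubated, without crosslinking, with an antibody, and the RNA recovered with it is sequenced. Per the labels, 1 library came from a pull-down with an antibody against LC3B, 1 from a pull-down with non-specific IgG, and 1 input library without antibody accompanied each of them. Libraries were made with a kit for very low amounts of polyadenylated RNA (SMART-Seq v4), per the labels' protocols. Each of the 4 groups holds 1 library, so no difference has a replicate check and no p-value was computed.

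The deposited counts are raw read counts per Ensembl gene, per the file headers, for 60676 genes. Digits were grouped with commas in both deposited tables; the commas were removed, after which each count was a whole number. The deposited TPM values (shares of each library after division by transcript length) were scaled by the authors within each library, per the file headers, with transcript lengths that are not given in the sources used here. Per the submitters' processing notes, cutadapt 2.8 and STAR 2.7.1a were used with build hg38. The counting tool, the annotation release, the strand setting and the treatment of duplicate and multi-mapping reads are not given in the sources used here. Reads from overlapping, antisense or near-identical genes may therefore have been divided between them in ways the tables do not show, and coordinates are those of the deposited tables.

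Counts were scaled by the total count of each library and are given in CPM, the usual unit for this share. Genes with a mean of at least 1 CPM over the 4 libraries were kept, which left 15108. For each gene and each of 4 comparisons (LC3B pull-down over IgG pull-down, each pull-down over its input, LC3B input over IgG input) the fold was given with an exact conditional binomial (Clopper-Pearson) 95% interval. A gene was called higher when the lower bound was at least 2, and lower when the upper bound was at most 0.5. LC3B-enriched genes were those called higher both over the IgG pull-down and over the LC3B input, and the mirror set was defined in the same way for IgG. An input-corrected ratio, the fold of the LC3B pull-down over its input divided by that of the IgG pull-down over its input, was computed with 0.5 added to each count and a log-normal counting interval. Where a library held 0 reads of a gene, the fold was computed with 3 reads in that library and is given as a bound; 3 reads correspond to 0.276 CPM in the IgG input, 0.278 in the LC3B input, 0.300 in the IgG pull-down and 0.287 in the LC3B pull-down. Intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Shares of the total count have exact binomial (Clopper-Pearson) intervals.

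For 19 gene lists the median of log2((CPM + 0.5)/(CPM + 0.5)) was placed among 10000 random lists of the same size drawn within 20 bins of mean expression; a list was called when its median lay outside the central 95% of these. This describes the 4 libraries and is no test across samples. The lists were ATG8 conjugation and autophagy initiation, autophagy receptors, lysosome, AU-rich-element and immediate-early mRNAs, nuclear-retained long non-coding RNAs, small nuclear and other structured RNAs, small nucleolar RNA host genes, cytosolic ribosomal proteins, mitochondrially encoded RNAs, nuclear-encoded oxidative phosphorylation, replication-dependent histones, extracellular matrix, homologous recombination, R-loop factors, SR-family splicing factors, mitosis, glycolysis, protein folding, and markers of other cell types.

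The comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 15 LC3B-enriched genes with the largest lower bound over IgG, the 10 genes lower in the LC3B than in the IgG pull-down with the smallest upper bound, the 5 higher and 5 lower genes of each pull-down over its input and of the input-corrected ratio, called and abundant list members, and FN1, PRMT1, MAP1LC3B, GAPDH, ACTB, MALAT1 and NEAT1. Features sharing a symbol with another feature were not named, and 1 gene that met the rule is not reported here. Alternatives were trimmed-mean (TMM) and median-of-ratios scaling, totals without mitochondrial genes and the 10 most abundant genes, no filter, a filter of 5 CPM, bounds of 4 and 0.25, thinning to the smallest total, deposited TPM, point folds without interval, and pseudocounts of 0.1 and 1. The TMM and median-of-ratios factors were computed from the published definitions of these methods in purpose-written code, not with the packages that first offered them, and served as scalings only. A total without mitochondrial genes alone, the genes of at least 100 CPM in the inputs, calls against both inputs and random lists matched on transcript length were added after seeing the data.

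The procedure was tested on simulated counts drawn with counting error alone (Poisson) from the real means and library sizes over 15108 genes. For the LC3B over the IgG pull-down, 90 of 100 genes changed 4-fold and 99 of 100 changed 8-fold were recovered, and 0 unchanged genes were called. For the LC3B pull-down over its input, 91 of 100 and 98 of 100 were recovered with 1 unchanged gene called; for the IgG pull-down over its input, 84 of 100 and 98 of 100 with 2; for the input pair, 86 of 100 and 98 of 100 with 0. The input-corrected ratio recovered 191 of 200 genes raised 8-fold. Real libraries differed by more than counting error, so these simulations give no rate of false calls for the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.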

Results

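The study asked which nuclear RNAs are recovered with LC3B, a ubiquitin-like protein that is attached to autophagosome membranes and is also found in the nucleus. Polyadenylated RNA was sequenced from an LC3B pull-down, an IgG pull-down that measures background, and an input for each, with 1 library per group and no replicates. Total counts were 10886762 in the IgG input, 10782146 in the LC3B input, 10000914 in the IgG pull-down and 10456770 in the LC3B pull-down. Depth was thus similar, but the number of genes with a read was not. Reads fell on 22947 genes in the IgG input, 23082 in the LC3B input and 23915 in the LC3B pull-down, against 14440 in the IgG pull-down.

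Mitochondrial RNA was largely lost in both pull-downs. Mitochondrial genes took 22.8% of the total count in the IgG input (95% exact binomial interval 22.779 to 22.829) and 20.8% in the LC3B input (20.748 to 20.796), but 1.76% in the IgG pull-down (1.757 to 1.773) and 0.774% in the LC3B pull-down (0.769 to 0.780). The inputs thus also held RNA from outside the nucleus. Whether the other RNAs recovered came from the nucleus cannot be told from these libraries. Ribosomal protein mRNAs took 2.75% (2.745 to 2.764) and 2.72% (2.714 to 2.733) of the inputs, 3.13% (3.122 to 3.144) of the IgG pull-down and 4.42% (4.407 to 4.432) of the LC3B pull-down. Of the counts outside mitochondrial genes they took 3.57% in the IgG input and 3.44% in the LC3B input. On that scale their share fell to 3.19% in the IgG pull-down and rose to 4.45% in the LC3B pull-down. Long non-coding RNAs rose from 2.05% and 2.15% in the IgG and LC3B inputs to 2.64% and 2.96% in the IgG and LC3B pull-downs. Of the counts outside mitochondrial genes they took 2.66%, 2.71%, 2.69% and 2.98% in the same order. The 10 most abundant genes held 24.4% of the IgG input, 22.4% of the LC3B input, 7.57% of the IgG pull-down and 6.42% of the LC3B pull-down.

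**Figure D1:**
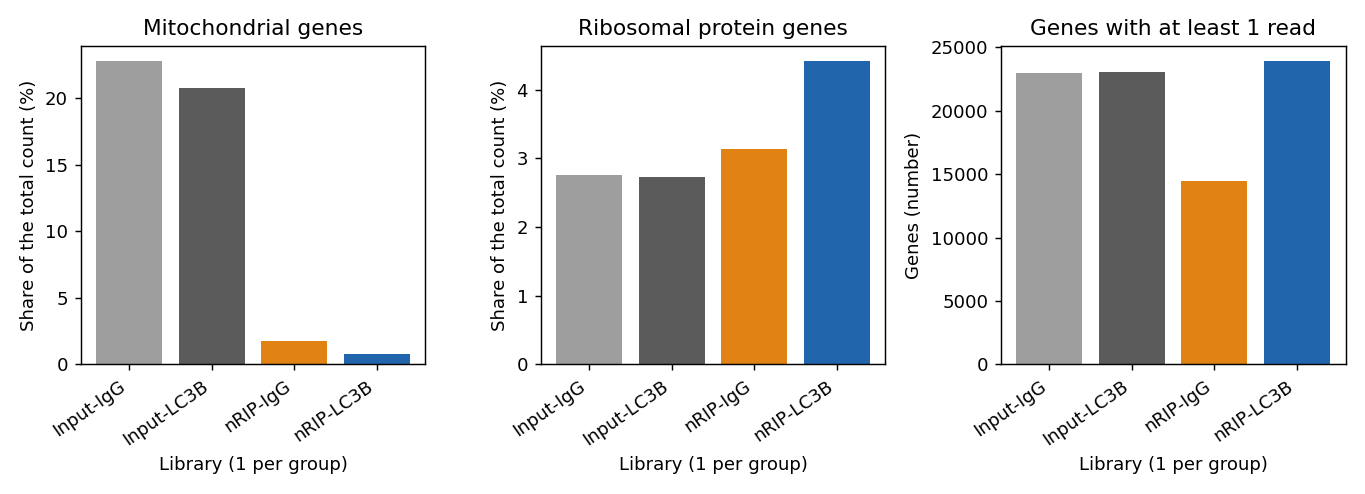
Bars give, for each of the 4 libraries (1 per group), the share of the total count in mitochondrial genes (%), the share in ribosomal protein genes (%) and the number of genes with at least 1 read. Mitochondrial genes hold 22.8% and 20.8% of the inputs against 1.76% and 0.774% of the IgG and LC3B pull-downs, and the IgG pull-down has reads on 14440 genes against 22947 or more in the others.

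The comparison of the LC3B with the IgG pull-down asks which RNAs were recovered above background. It called 5055 of 15108 genes higher and 1430 lower in the LC3B pull-down. Of the 5055 higher genes, 2770 had 0 reads in the IgG pull-down and 4113 were also called lower in the IgG pull-down than in its own input. MALAT1 and NEAT1, nuclear long non-coding RNAs, were both lower with LC3B: MALAT1 (ENSG00000251562, chromosome 11, 65497688 to 65506516) had a fold of 0.211 (95% counting interval 0.206 to 0.216) and NEAT1 (chromosome 11, 65422774 to 65445540) a fold of 0.395 (0.355 to 0.440). The mRNAs of both ferritin subunits, which form the iron storage complex and were picked out after their values were seen, were lower too, FTL at 0.172 (0.170 to 0.175) and FTH1 at 0.305 (0.301 to 0.309). Of the mRNAs described as bound by LC3 or LC3B, FN1 (fibronectin) had a fold of 0.921 (0.812 to 1.04) and PRMT1 (an arginine methyltransferase) a fold of 0.950 (0.904 to 0.997), and neither was called. MAP1LC3B, which encodes LC3B, stood at 0.607 (0.571 to 0.644), GAPDH at 1.31 (1.30 to 1.33) and ACTB at 1.79 (1.77 to 1.81), all uncalled.

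Of the 10 genes furthest below IgG, 8 had at most 9 reads in either input; POC1B-GALNT4 had 20 and 30 and AL390038.1 had 72 and 86 in the IgG and LC3B inputs. IGDCC3 had 254 reads in the IgG pull-down, 3 in the LC3B pull-down, and 1 and 3 in the IgG and LC3B inputs, a fold of 0.0113 (0.00231 to 0.0334). ACTC1, cardiac actin, had 258 against 3 reads (fold 0.0111, 0.00228 to 0.0329), LINC01607 had 262 against 2 (fold 0.0073, 0.00088 to 0.0266), and POC1B-GALNT4, a read-through of neighbouring genes, had 210 against 1 (fold 0.00455, 0.000115 to 0.0257). With 0 reads in the LC3B pull-down, AL390038.1 was at least 90.6-fold lower, FAM95B1 at least 63.8-fold, DHH (a hedgehog ligand) at least 58.6-fold, AL133467.3 at least 51.2-fold, AP000781.2 at least 48.4-fold and OR4C6 (an olfactory receptor) at least 41.5-fold. Of the 1430 lower genes, 267 were below 1 CPM in the inputs.

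Genes without reads in the IgG pull-down were not rare ones alone. Among 3649 genes at 10 to 30 CPM in the inputs, 454 (12.4%) had 0 reads in the IgG pull-down and 0 did in the other libraries; at 1 to 3 CPM, 1088 of 2373 (45.8%) had none in the IgG pull-down against 8 in the LC3B pull-down. Across the 15108 genes, which are not independent replicates, log2 CPM correlated at 0.988 between the inputs and at 0.944 between the LC3B pull-down and its input, and at 0.775 for the IgG pull-down with its input and with the LC3B pull-down. Among genes of at least 100 CPM these values were 0.995 between the inputs, 0.755 for LC3B and 0.738 for IgG with its input, and 0.783 between the pull-downs. Among the 1795 genes of at least 100 CPM in the inputs, a set chosen after the data were seen, 135 were called higher and 132 lower in the LC3B than in the IgG pull-down.

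**Figure D2:**
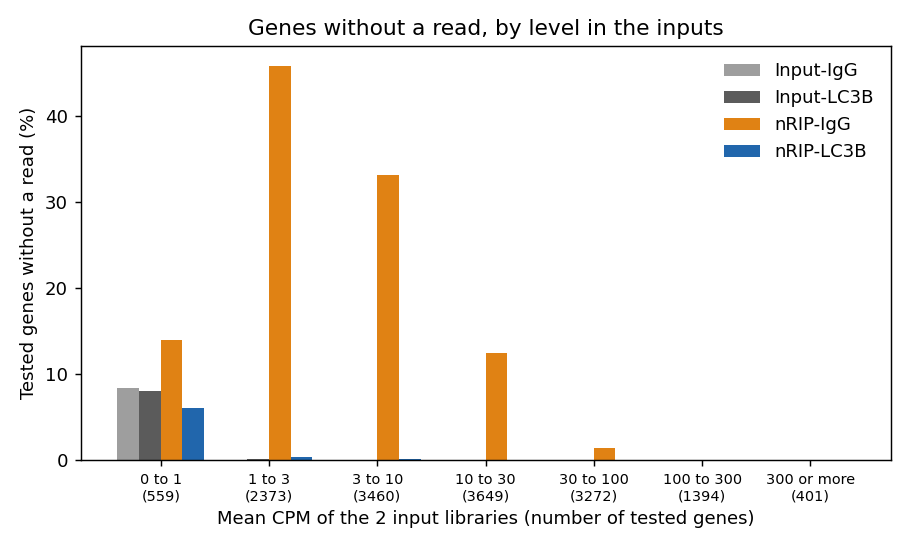
Bars show the percentage of tested genes without a read in each of the 4 libraries, for classes of mean CPM in the 2 inputs (number of genes in brackets). In the IgG pull-down the share is 45.8% at 1 to 3 CPM and 12.4% at 10 to 30 CPM.

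Set against its own input, the LC3B pull-down showed smaller changes, with 880 genes higher and 265 lower. The lowest were transcripts of the mitochondrial genome, such as MT-ATP6 at 0.0118 (0.0109 to 0.0127), MT-ND5 at 0.0177 (0.0163 to 0.0192), MT-ND4 at 0.0190 (0.0178 to 0.0203) and MT-ND2 at 0.0209 (0.0186 to 0.0234), together with MTATP6P1, a nuclear copy of mitochondrial sequence, at 0.0125 (0.0107 to 0.0144). Of the 5 highest, AC005538.2 (at least 69.8-fold), H3C14 (a histone H3 gene, at least 45.4-fold), AL671762.1 (at least 35.4-fold) and AC087721.2 (at least 29.2-fold) had 0 reads in the LC3B input but 129, 115, 17 and 131 in the IgG input. Reads of these genes may have been divided differently between overlapping or near-identical genes, and their folds are uncertain. AP002748.5 had 94 reads in the LC3B pull-down and 0 in both inputs, at least 32.3-fold. FN1 stood at 1.39 (1.21 to 1.59) and PRMT1 at 1.59 (1.505 to 1.681), both uncalled, while MALAT1 fell to 0.477 (0.465 to 0.489). The loss of mitochondrial RNA raises the CPM of the remaining genes in a pull-down: the median gene had a log2 ratio over input of 0.32, and of 0.01 with totals taken without mitochondrial genes, a scaling added after seeing the data. With that scaling 215 genes were higher and 694 lower, against 259 and 635 with TMM and 202 and 724 with median-of-ratios scaling, so that the balance of higher and lower genes was turned around.

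The IgG pull-down differed from its input at more genes, 2355 higher and 4440 lower. The lowest were ABHD14B, an abundant mRNA with 768 reads in the IgG input and 0 in the pull-down (at least 235.2-fold lower), PHF3 (at least 176-fold), CTTNBP2NL (at least 167-fold), GINS1, a replication factor (at least 164-fold), and NUP58, a nuclear pore component (at least 164-fold). The highest by lower interval bound were genes with 0 to 2 reads in the IgG input. FAM95B1 was at least 66.4-fold higher, AC008555.2 at least 57.3-fold and AC104024.1 at least 56.6-fold, IGDCC3 had a fold of 276 (49.2 to 10964) and AL022344.1 a fold of 156 (42.9 to 1296). PRMT1 stood at 1.83 (1.73 to 1.93) and FN1 at 1.69 (1.47 to 1.95), both uncalled and both above their folds in the LC3B pull-down, and MALAT1 was higher at 2.09 (2.06 to 2.13), a call lost under each other scaling. Without mitochondrial genes in the totals, 1488 genes were higher and 5014 lower. Over 15093 genes without the mitochondrial ones, the log2 ratios of the pull-downs over their own inputs, which share no library, correlated across genes at 0.154, and at 0.444 over 1783 such genes of at least 100 CPM.

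**Figure D3:**
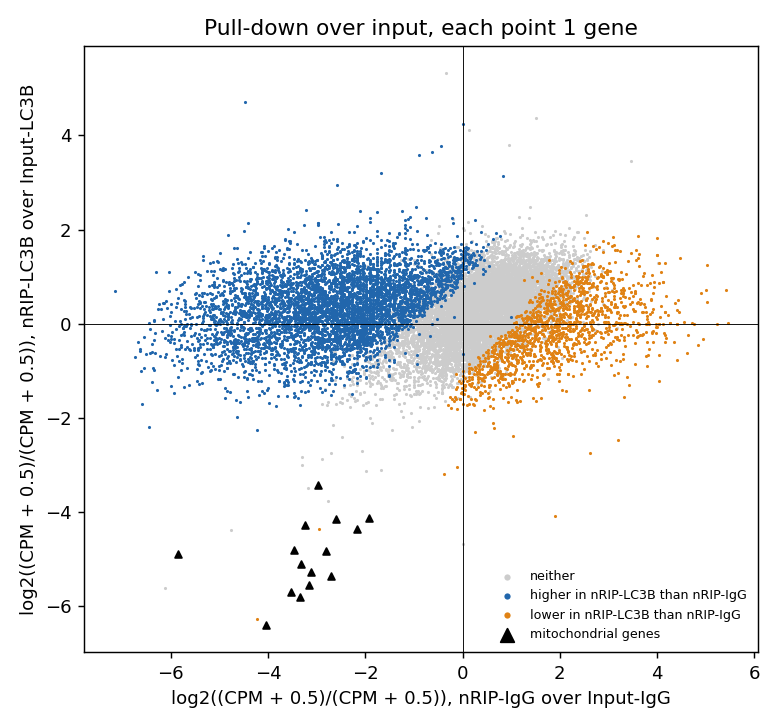
Each point is 1 tested gene, with the log2 ratio of the IgG pull-down over its input on the horizontal axis and that of the LC3B pull-down over its input on the vertical axis (0.5 CPM added); colours mark the 5055 and 1430 genes called higher and lower in the LC3B than in the IgG pull-down, triangles the mitochondrial genes. The standard deviation over genes is 1.94 along the horizontal and 0.73 along the vertical axis.

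The inputs were alike: 19 genes were called higher and 19 lower in the LC3B input than in the IgG input, and 0 among genes of at least 100 CPM. Their counts nonetheless differed by more than counting error, with a median chi-square per gene 2.75 times that of sampling alone, so they were separate libraries and were kept apart. As groups, lysosomal (percentile 100), extracellular matrix (99.9), AU-rich-element (99.5), SR-family (99.4) and small nucleolar host (97.6) transcripts lay above matched random lists in the LC3B input over the IgG input, and mitochondrially encoded RNAs (0), ribosomal protein mRNAs (0.08) and glycolysis (2.04) below, with 0 members called. These shifts were small, the largest median log2 ratios being 0.19 for lysosome and 0.17 for extracellular matrix. List calls thus also arose between inputs without antibody, so a call alone does not mark an effect of a pull-down. The small nucleolar host call was lost without a filter (percentile 97.2), with a filter of 5 CPM (97.1), after thinning (97.2) and among genes of at least 100 CPM (89.75), and the glycolysis call with a filter of 5 CPM (5.36), in TPM (5.75) and among genes of at least 100 CPM (9.54). Lists called only under alternatives were nuclear-retained RNAs with a filter of 5 CPM (98.3), oxidative phosphorylation with that filter (97.7) and among genes of at least 100 CPM (99.3), protein folding after thinning (98.7) and among genes of at least 100 CPM (99.7), and histones among the latter (98.6).

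Genes higher over both the IgG pull-down and the LC3B input numbered 343, of which 262 were protein coding and 71 long non-coding. The mirror set for IgG held 1049. PLOD3, a collagen lysyl hydroxylase (ENSG00000106397, chromosome 7, 101205977 to 101218420), led with 844 reads against 1 in the IgG pull-down, a fold of 807 (144 to 31920.2), and 2.59-fold (2.28 to 2.95) over its input. PPP6R1, a phosphatase subunit (chromosome 19, 55229779 to 55259017), had a fold of 593 (106 to 23458), the transcribed pseudogene AL390719.1 a fold of 508 (90.8 to 20096), SLC38A10, an amino acid transporter, 437 (78.1 to 17301), and TSPAN5, a tetraspanin, 306 (84.2 to 2529). The other named genes had 0 reads in the IgG pull-down. C4BPB, a chain of the complement regulator C4BP, was at least 142-fold higher, ARC, an immediate-early gene of neurons, at least 138-fold, ARMCX2, AVPI1 and DUS2 (a tRNA dihydrouridine synthase) each at least 137-fold, the collagen COL8A1 at least 135-fold, NOTCH2NLA at least 124-fold, CA11 at least 100.1-fold, CXXC5 at least 97.2-fold and ATG4D, a protease that processes LC3-family proteins, at least 90.2-fold. NOTCH2NLA has near-identical paralogs, and its count is uncertain. Over the input these 15 genes lay between 2.48-fold (CXXC5) and 4.61-fold (AVPI1, 3.69 to 5.81). With totals without mitochondrial genes 102 genes met both conditions, all among the 343, and 4 of the 15 named genes did: AVPI1, C4BPB, CA11 and SLC38A10. Both conditions use the LC3B library. Independent lists of these sizes would share 294 genes, and part of the excess may come from the shared library. For the IgG mirror set independent lists would share 223 genes, against the 1049 found, a larger excess than with LC3B. Its conditions likewise share the IgG library. Simulated libraries with counting error alone shared 0 in each of 100 draws, but libraries differed by more than counting error here, so this is no reference for the 343.

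The input-corrected ratio called 4359 genes higher and 1220 lower. The highest were H3C14 (at least 1598-fold, with 0 reads in the LC3B input and in the IgG pull-down), ABHD14B (at least 381-fold), TMEM184C (at least 235.3-fold), and CCDC80 and PPP6R1, with 1 read each in the IgG pull-down and ratios of 675 (135 to 3366) and 430.3 (85.8 to 2157). The lowest were AL390038.1, THSD8, RN7SK (the RNA of the 7SK particle that holds back transcription elongation), AC013275.1 at 0.00386 (0.00044 to 0.0339) and POC1B-GALNT4 at 0.00454 (0.000828 to 0.0249). RN7SK was not called over the LC3B input. It is 1 of the 3 structured RNAs measured, and 1 of these was called higher in the LC3B than in the IgG input. The ratio of RN7SK is therefore uncertain. FN1 had a ratio of 0.820 (0.676 to 0.995) and PRMT1 of 0.871 (0.805 to 0.942), both uncalled.

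Ribosomal protein mRNAs were shifted up with LC3B as a group. Over the LC3B input 20 of 78 were higher and 0 lower, with a median log2 ratio of 0.78, above all 10000 matched random lists, whose median was 0.37. RPS3 stood at 2.94 (2.85 to 3.03) and RPS29 at 2.53 (2.38 to 2.69). Over the IgG pull-down 18 were higher and 0 lower (median 0.66, above all random lists), led by RPS29 at 3.58 (3.33 to 3.85) and RPS25 at 3.31 (3.12 to 3.52). In the IgG pull-down over its input the list median of 0.01 lay below all random lists, with 1 member higher, RPL8 at 2.20 (2.14 to 2.26). Without mitochondrial genes in the totals 2 members remained higher over the LC3B input and 0 lower, and over the IgG input 0 were higher and 5 lower. The list kept its place relative to random lists under each scaling tried. A scaling shifts list members and random genes alike, so this place could hardly change and the result adds nothing. Many of these genes have processed pseudogenes, with which reads may be shared.

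The 15 mitochondrially encoded RNAs were lower than input in both pull-downs without exception, with median log2 ratios of -4.89 for LC3B and -3.16 for IgG. In the LC3B relative to the IgG pull-down 12 were lower and 0 higher, as for MT-CO2 at 0.146 (0.139 to 0.154), whereas the ribosomal RNA MT-RNR2 stood at 1.80 (1.76 to 1.83).

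Extracellular matrix mRNAs had a median log2 ratio of 0.96 over the LC3B input, above all random lists, with 6 of 25 higher and 0 lower. Among them were LOXL2, a collagen crosslinking enzyme, at 3.10 (2.84 to 3.39), TGFBI at 2.89 (2.75 to 3.03) and COL1A1 at 2.77 (2.60 to 2.95). In the IgG pull-down the median was 0.60 (percentile 94.1, 8 higher and 3 lower), with COL4A2 at 3.77 (3.36 to 4.23), and between the pull-downs 0.58 (percentile 95.3, 8 higher and 1 lower). Without mitochondrial genes in the totals 3 members were higher and 0 lower over the LC3B input, and 3 higher and 4 lower over the IgG input. Among genes of at least 100 CPM the list was not called over the LC3B input (percentile 96.0) but was between the pull-downs (99.1). Over input, lysosomal mRNAs had medians of 0.59 with LC3B (percentile 96.5, 4 of 28 higher and 0 lower) and 0.61 with IgG (percentile 94.6, 7 higher and 1 lower), and were not called, except over the LC3B input among genes of at least 100 CPM (percentile 98.2). GRN, the progranulin precursor of lysosomal granulins, was higher in both, at 2.64 (2.45 to 2.85) and 3.99 (3.71 to 4.30), and LAMP1, a lysosomal membrane protein, with LC3B alone, at 2.37 (2.04 to 2.76) against 0.511 (0.401 to 0.646) with IgG, a difference that was not tested across samples. Without mitochondrial genes in the totals 0 lysosomal members, and so neither of these, were called over the LC3B input.

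Glycolytic mRNAs had a median of 0.75 over the LC3B input (percentile 98.5), with 5 of 17 higher, among them ENO1 at 2.39 (2.34 to 2.43) and ALDOA at 2.33 (2.26 to 2.41); the IgG median of 0.43 lay at percentile 73.6. Nuclear-encoded oxidative phosphorylation mRNAs had a median of 0.61 over the LC3B input (percentile 98.7, 7 of 38 higher), as for NDUFV1 at 2.52 (2.31 to 2.76), and of 0.52 with IgG (percentile 85.7, 10 higher), as for UQCRC1 at 4.60 (4.40 to 4.81). Without mitochondrial genes in the totals 0 members of either list were higher over the LC3B input. The glycolysis call was lost in TPM (percentile 94.2) and among genes of at least 100 CPM (94.75), and the oxidative phosphorylation call among the latter (89.6).

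Mitotic mRNAs lay below random lists in both pull-downs. Their median log2 ratio was -0.45 over the LC3B input and -0.55 over the IgG input, both below all random lists. With LC3B 1 of 32 was lower, CENPE, a kinetochore motor, at 0.421 (0.367 to 0.482); with IgG 9 were lower, as KIF14 at 0.0213 (0.00687 to 0.0505), and 3 higher, AURKB, CCNB1 and PLK1. Between the pull-downs the median was 0.38 (percentile 99.0, 4 higher and 1 lower), a call lost in TPM (percentile 73.2) and among genes of at least 100 CPM (69.7); with median-of-ratios scaling 1 was higher and 3 lower. Without mitochondrial genes in the totals 7 members were lower over the LC3B input, and 1 was higher and 13 lower over the IgG input. Nuclear-retained long non-coding RNAs lay lower than random lists over the LC3B input (median -0.34, percentile 0.46, 1 of 14 lower), a call lost without a filter on low genes (percentile 5.21), with a filter of 5 CPM (percentile 6.29), in TPM (percentile 4.66) and among genes of at least 100 CPM (percentile 6.13), and not over the IgG input (median 0.25, percentile 66.9). Between the pull-downs 4 of the 14 were higher and 3 lower (median -0.09, percentile 20.6). The list of small structured RNAs, of which 3 of 24 were measured, was called lower over the LC3B input (median -2.87, percentile 0, 2 lower) and between the pull-downs (median -2.23, percentile 0.66, 2 lower), but not over the IgG input (median -0.39, percentile 62.9). Of the 3, 1 was called higher in the LC3B input than in the IgG input. In addition, 2 had 0 reads in the IgG pull-down or the IgG input, so the contrast between the inputs is uncertain. RN7SL1, the RNA of the signal recognition particle, was lower over the LC3B input at 0.0928 (0.0596 to 0.139), and RN7SL2 at least 10.99-fold lower, with 0 reads in both pull-downs.

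Autophagy genes were not called as a group on total counts. The ATG8 conjugation and initiation list had medians of 0.31 over the LC3B input (percentile 51.8, 2 of 30 higher and 1 lower), 0.03 over the IgG input (percentile 42.0) and 0.52 between the pull-downs (percentile 85.0, 11 higher and 1 lower). ATG101, a subunit of the ULK1 complex, was higher over the LC3B input at 3.33 (2.95 to 3.78), and RB1CC1, another subunit, lower at 0.402 (0.351 to 0.460). Autophagy receptors had medians of -0.07 over the LC3B input (percentile 5.05) and -0.12 between the pull-downs (percentile 27.6), with 0 of 18 called over the LC3B input. In TPM the receptors lay below random lists over the LC3B input (percentile 0.93), and without mitochondrial genes in the totals 2 were lower.

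Of the remaining 8 lists, none was called in a pull-down over its input or between the pull-downs on total counts. Some were called under alternatives: homologous recombination lower over the LC3B input with TMM and median-of-ratios scaling and without mitochondrial genes in the totals (percentile 2.47 in each), without a filter and after thinning (1.15), AU-rich-element mRNAs higher between the pull-downs in TPM (97.7), and markers of other cell types higher over the IgG input without a filter (99.6) and over the LC3B input among genes of at least 100 CPM (98.3). The median over the LC3B input was 0.47 for AU-rich-element and immediate-early mRNAs (percentile 83.6), 0.53 for small nucleolar RNA host genes (percentile 86.2), 0.06 for replication-dependent histones (percentile 9.75), -0.03 for homologous recombination (percentile 2.54), -0.01 for R-loop factors (percentile 8.22), 0.10 for SR-family splicing factors (percentile 11.3) and 0.37 for protein folding (percentile 58.7). Of 33 homologous recombination genes, 1 was higher and 3 were lower over the LC3B input, BRCA2 among the lower at 0.371 (0.304 to 0.451). Between the pull-downs 10 of them were higher and 4 lower. HSPA1A, a heat-shock chaperone that has a near-identical copy in HSPA1B, was higher at 2.45 (2.24 to 2.68) over the LC3B input, a call lost under each other scaling, as were those of the other 3 protein folding genes without mitochondrial genes in the totals. Markers of other cell types were measured for 5 of 19 genes (median 0.55 over the LC3B input, percentile 72.5); the haemoglobin gene HBA2 had 57 reads in the IgG pull-down, 1 in the IgG input and 0 in the LC3B libraries.

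Random lists matched on expression alone do not allow for transcript length, with which both pull-downs fell. With lists matched on length as well, an alternative added after seeing the data, mitosis stayed low over the LC3B and IgG inputs (percentiles 0.02 and 0.04), and ribosomal protein mRNAs (99.97), extracellular matrix (100) and glycolysis (99.9) stayed high over the LC3B input. Calls over the LC3B input were lost for oxidative phosphorylation (91.2) and nuclear-retained RNAs (2.97) and gained for lysosome (98.4). Extracellular matrix was then also called over the IgG input (99.3). Replication-dependent histones were called lower over the LC3B and IgG inputs (1.24 and 1.87) and higher between the pull-downs (99.4). In the input pair glycolysis was no longer called (4.32), and oxidative phosphorylation was (98.95). Members without a length estimate were left out, so some lists changed as well. Histones went from 21 to 19 members. Their median went from 0.53 to 0.91 between the pull-downs and stayed at 0.06 over the LC3B input. Nuclear-retained RNAs went from 14 to 13 (median over the LC3B input -0.34 to -0.14) and glycolysis from 17 to 16. Apart from histones over the LC3B input, length matching and lost members cannot be told apart for these lists.

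**Figure D4:**
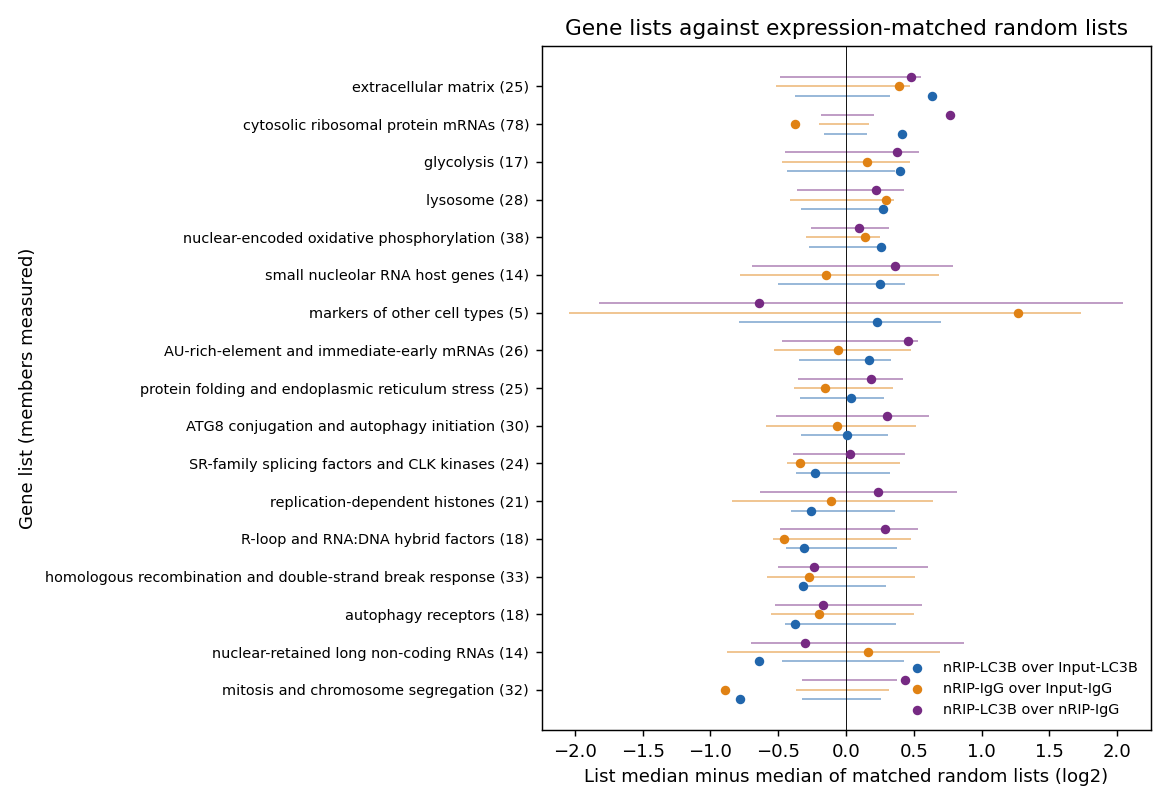
Points give the median log2 ratio of each gene list minus the median of 10000 matched random lists (horizontal axis, log2) for 3 comparisons, and lines span the central 95% of the random lists; the number of measured members stands in brackets. The mitochondrially encoded RNAs and the structured RNAs are not drawn. Ribosomal protein mRNAs lie at 0.41 over the LC3B input and at -0.38 over the IgG input, and mitosis at -0.78 and -0.89.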

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

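The tests of the IgG library's complexity, of LC3B binding and of the ratio of totals were chosen after the result was seen; the thinning was planned before. 22 named genes were called in opposite directions in the LC3B and the IgG pull-down over their own inputs, and the difference was not tested across samples. They include the 15 named LC3B-enriched genes, whose rule picks genes high with LC3B and low with IgG. Opposite calls of these 15 thus follow largely from the choice. Over all tested genes, 149 were higher with LC3B and lower with IgG over input, against 259 for independent lists. The reverse held for 8, against 41.3. Genes higher in both numbered 238, against 137, and lower in both 108, against 77.9. The input-corrected ratio was at least 174-fold for C4BPB, 155-fold for AVPI1, 149-fold for ARC, 148-fold for ARMCX2, 147-fold for CA11, 139-fold for COL8A1, 133-fold for DUS2, 105-fold for CXXC5, 99.4-fold for ATG4D and 96.6-fold for NOTCH2NLA, which had 0 reads in the IgG pull-down, and at least 1598-fold for H3C14, which also had 0 in the LC3B input. With 1 or 2 reads in the IgG pull-down it was 430.3 for PPP6R1, 409.7 for PLOD3, 316 for SLC38A10, 241 for TSPAN5 and 227 for AL390719.1. At higher counts it was 6.61 for HSPA1A. In the other direction it was 0.228 for MALAT1, 0.183 for FTL and 0.00454 for POC1B-GALNT4, and at most 0.00915 for AL390038.1 and 0.00987 for THSD8, which had 0 reads in the LC3B pull-down. With totals without mitochondrial genes, 8 of the 22 kept opposite calls: AVPI1, C4BPB, CA11, SLC38A10, H3C14, AL390038.1, POC1B-GALNT4 and THSD8. FTL and MALAT1 were then no longer called over the IgG input, and the other 12 no longer over the LC3B input.

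The 5055 genes higher in the LC3B than in the IgG pull-down may mostly be genes that the IgG library failed to sample. If LC3B bound these RNAs in preference to other genes, they should stand out over input in the LC3B pull-down. Their median log2 ratio over input exceeded that of all other genes of the same input level by 0.0430. The 95% bootstrap interval over genes was 0.0103 to 0.0732, and even its upper bound lies below the limit of 0.2 for binding. This limit was set after the result was seen. With the genes called lower left out of the reference, the difference was -0.0285 (-0.0610 to 0.0107). The LC3B library enters both the call and this difference, which favours a larger one. A smaller total of the IgG library was argued against, since the total of the LC3B pull-down was 1.046 times that of the IgG pull-down, where over 2 was needed. Thinning to the smallest total left 5042 genes higher but removed too few reads to decide anything. Low complexity of the IgG library, meaning few distinct RNA molecules, has the small difference it needs, but little RNA recovered with IgG and a failed library step would look the same in 1 library. Binding by LC3B stays open for smaller sets such as the 343 genes above both controls, for which this test says nothing. Binding of the called and the other genes alike also stays open, since CPM are shares and no difference would then arise.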

How the results depend on the processing

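The genes of at least 100 CPM, the total without mitochondrial genes alone and calls against both inputs were chosen after seeing the data. Each count names the higher and then the lower genes. No paired analysis was possible because each group holds 1 library. LC3B over IgG pull-down (5055 and 1430): a filter of 5 CPM left 2735 higher, genes of at least 100 CPM 135 and 132, and bounds of 4 and 0.25 left 368 lower. LC3B pull-down over input (880 and 265): TMM gave 259 and 635, median-of-ratios 202 and 724, totals without mitochondrial and top 10 genes 215 and 694, totals without mitochondrial genes 215 and 694, TPM 1834 and 744, point folds 2200 and 627, genes of at least 100 CPM 116 and 82, and bounds of 4 and 0.25 19 and 39. IgG pull-down over input (2355 and 4440): totals without mitochondrial and top 10 genes gave 1502 higher, without mitochondrial genes 1488 higher, a filter of 5 CPM 2310 lower, genes of at least 100 CPM 184 and 109, and the wider bounds 595 higher. Input pair (19 and 19): no filter gave 65 and 42, a filter of 5 CPM 2 and 5, TPM 275 and 157, point folds 184 and 98, genes of at least 100 CPM 0 and 0, and the wider bounds 5 and 8. Input-corrected ratio (4359 and 1220): a filter of 5 CPM gave 2513 higher, TPM 2377 lower, point folds 2266 lower, genes of at least 100 CPM 112 and 128, and the wider bounds 2689 and 270. LC3B-enriched genes (343): TMM gave 119, median-of-ratios 96, totals without mitochondrial and top 10 genes 102, without mitochondrial genes 102, TPM 855, point folds 1024, genes of at least 100 CPM 23, and the wider bounds 10. The IgG mirror set (1049) became 698 with a filter of 5 CPM, 25 among genes of at least 100 CPM and 269 with the wider bounds. Stricter filters and bounds test or admit fewer genes by construction, and totals without mitochondrial genes differ through the mitochondrial share. For TMM, median-of-ratios, TPM and point folds the cause was not tested.

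Without mitochondrial genes the 10 most abundant genes held 6.27% of the IgG input, 6.08% of the LC3B input, 7.28% of the IgG pull-down and 6.47% of the LC3B pull-down. Over all gene lists and comparisons, 797 alternatives left a list called, or uncalled, as on total counts. A call was lost in 17 and gained in 17. In 1 more the list turned: histones in the input pair. Uncalled on total counts, they lay 0.14 above random lists among genes of at least 100 CPM. Many of the 797 were lists uncalled both ways, which says nothing about their direction. Scalings shift list members and random genes alike and could hardly change a call, so the 797 measure stability only weakly. The log2 ratio of named genes between the LC3B and IgG pull-downs was labelled the same in 1356, weaker in 46 and stronger in 17, and 1 turned: SMC2, at -0.00835 in TPM; the cause was not tested. Over input fewer calls held: under each other scaling 4 of the 15 named enriched genes stayed enriched, and 8 of 22 named genes kept opposite calls in the pull-downs. Depth limits folds against 0 reads to bounds, and with 1 library per group no alternative measures the spread between samples.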

Other observations

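The tests of length were chosen after the result was seen; the test of gene families was written down after the list results but before its own values were computed. Among the 1783 non-mitochondrial genes of at least 100 CPM in the inputs, 12 of those higher and 12 of those lower with LC3B than with IgG were picked out after their values were seen. On the higher side, SLC16A1, a lactate transporter, had a fold of 186 (94.4 to 433), the transcription factor STAT3 48.7 (32.6 to 76.4), the mitotic kinase NEK7 22.8 (14.2 to 38.8) and the chromatin protein CBX1 8.73 (7.32 to 10.48). The LC3B pull-down over its input stood at 1.35, 1.19, 0.402 and 1.04, and the IgG pull-down over its input at 0.00871, 0.0228, 0.0160 and 0.127. On the lower side, COMMD10 stood at 0.208 (0.189 to 0.229), the iron-sulfur scaffold ISCU at 0.219 (0.202 to 0.238) and PRKRA, a double-stranded RNA-binding protein, at 0.255 (0.234 to 0.277).

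Both pull-downs fell with transcript length, estimated as the deposited count over the deposited TPM in the LC3B input. This input is also the denominator of the LC3B ratio, but it does not enter the IgG ratio. The estimate is rough, since count over TPM was not constant between libraries. SMC2 had a log2 ratio of LC3B over IgG of 1.12 with TMM scaling but of -0.00835 in TPM. Across the 1783 genes, which are not independent replicates, the rank correlation of the length estimate with the log2 ratio over input was -0.33 for LC3B and -0.32 for IgG. Over the 13484 genes with an estimate it was -0.24 and -0.25, but the median of the longest 20% was 0.03 for LC3B and -1.01 for IgG, and LC3B over IgG rose with length (0.167). A preference of the LC3B antibody was argued against, since among the 1783 genes the correlations differed by -0.0104 (95% bootstrap interval -0.0487 to 0.0425) and a difference beyond -0.1 was needed. The correlation for LC3B without mitochondrial genes, -0.241 over 13484 genes, decided nothing about a loss of mitochondrial RNA, since leaving out 15 of 13499 genes could hardly move it. RNA fragmentation and preferential amplification of short cDNA could each give such a trend and stay open; they were not tested.

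Secretory and lysosomal mRNAs had medians above most random lists in both pull-downs over input, and retention of mRNAs translated at the endoplasmic reticulum was a candidate explanation. It needed 3 families of membrane or secreted proteins to exceed random lists matched on expression and length in both pull-downs, and 0 of the 3 did. In the LC3B pull-down, solute carriers (143 genes, percentile 99.9) and integrins, laminins and collagens (40 genes, percentile 100) exceeded them, and TMEM genes (153 genes, percentile 88.1) did not; in the IgG pull-down the percentiles were 11.5, 94.6 and 61.3. Solute carriers and integrins, laminins and collagens were also raised in the LC3B input over the IgG input (percentiles 99.99 and 99.98). The controls, SLC25 mitochondrial carriers and ZNF genes, lay at percentiles 40.8 and 0.28 with LC3B. The test decided nothing: the lysosomal list itself missed this bar in the IgG pull-down with the same matching (percentile 96.8), and the collagens are shared with the extracellular matrix list that raised the question. Retention, in both pull-downs or with LC3B alone, stays open. In the LC3B over the IgG pull-down, solute carriers lay at percentile 99.2 (median log2 ratio 1.12, random lists 0.61), integrins, laminins and collagens at 64.6 and TMEM genes at 49.1; no difference was tested across samples.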
